A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

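Total RNA from budding yeast (Saccharomyces cerevisiae) was measured on Affymetrix expression arrays, 1 array per sample and 1 colour (biotin-labelled cRNA made from about 20 µg of total RNA). The 2 samples form 1 group, replicates 1 and 2 of the histone H3 K4,36,79R mutant after 18 hours in glucose. The labels' protocols state that the cells were harvested at an OD600 of 0.5 to 0.7, and the series' design text states that the replicates were separate cultures. Wild-type cultures and the other time points named in that text were not analysed here, so no comparison between groups was made.

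The deposited values are linear intensity values, 1 per probe set, made by the authors with MAS5 per the submitters' processing notes. MAS5 is an Affymetrix algorithm that subtracts mismatch signal from perfect-match signal, combines the probe pairs of a probe set and scales each array to a common trimmed mean. Its version, background settings and scaling target are not given in the sources used here. In each deposited column every signal was a whole multiple of 1 step, to within 9.3e-06 of a step, and the step was 0.0524 on replicate 1 and 0.0521 on replicate 2. If a step stood for the last decimal of a MAS5 signal kept to 1 decimal, the trimmed mean (2% left out at each end) would be 125.1 on both arrays, and the deposited values would be those signals multiplied by 0.524 and 0.521. What these factors were set to is not stated. One factor per array moves every gene of that array alike. Detection calls were not used here, and the precision of a value is limited by the number of arrays.

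Each array gave 9335 probe sets, of which 60 are controls. The platform annotation, which can be old, assigned 1 gene symbol to 6504 probe sets, several symbols to 328 and none to 2503. Of the 6504 symbols, 6504 matched the RefSeq gene table of assembly R64 through their gene identifier, and 0 needed an update. They named 5656 genes, and 315 of these had several probe sets, of which the one with the highest mean log2 signal was used. Probe sets with several symbols were left out of the lists. The 6 that detect histone H2A, H3 and H4 genes are given as shared probe sets, since each of those proteins has a pair of genes. Neither the deposited files nor the labels name a genome build. Start positions in the RefSeq table served only to order the genes along each chromosome, and no coordinates are given.

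Signals were used on the log2 scale as deposited. Although MAS5 scales each array, the deposited trimmed means were 65.6 on replicate 1 and 65.2 on replicate 2. A small constant therefore remains in every log2 difference, and it can make up all of a median close to 0. Percentiles are not affected, because the random lists carry the same constant. A gene's level is the mean and SD of its 2 signals. Levels of different genes were not tested against each other, because probe sets differ in affinity. Counts above background do set each probe set against the signals of others, and so describe detection and not level. The agreement of the arrays was described with Pearson's r and Spearman's rho across probe sets, the SD of the log2 difference and the count of probe sets over 2-fold apart. The 29 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. For each list with at least 5 genes left, the median log2 difference (replicate 2 minus replicate 1) was placed among 10000 random lists of the same size matched on mean signal in 20 bins. This was done on the 4092 genes with a mean signal of at least 21.6, a threshold that left out the dimmer part of the probe sets. A list was said to stand apart below the 2.5th or above the 97.5th percentile. With 1 array on each side no p-value was computed, and a percentile describes these 2 arrays only.

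Background was taken as the 95th percentile of 13 foreign probe sets, 4 for mouse genes and 9 for the antisense strand of bacterial controls. For genes near chromosome ends the planned distance in kb was replaced by gene order, the 10 outermost protein-coding genes of each chromosome arm. This was done because the deposited data name no build, although the RefSeq table used for the order has one. The design had assumed coordinates. Shares carry 95% Wilson intervals, which cover counting error over genes only.

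The list procedure was tested on simulated data made by shuffling the real differences of the 4092 genes within signal bins and shifting random lists, 200 per setting. With no shift it called 4.5% of lists of 10 genes and 5.0% of lists of 30. With a shift of 0.1 it called 46.5% and 92.0%, and with a shift of 0.2 it called 95.0% and 100.0%. The rate with no shift was close to fixed in advance, because the shuffling used the same bins as the random lists. The shuffling also broke any likeness between probe sets with neighbouring numbers. These rates therefore do not cover real lists whose genes vary together.

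The text names every measured gene of the histone, galactose and both mating-type-specific lists and 16 single genes. It also draws on the 10 genes with the largest difference in each direction and the 3 genes of highest mean signal in each other list. Alternatives were median centring, quantile normalization, loess on the mean signal (span 0.4), an offset of 50, other filters on dim probe sets, the mean of a gene's probe sets, other background thresholds and each array alone. Chosen after seeing the data were 5 and 15 outermost genes, a threshold from the sporulation list, and leaving out 2 ranges of probe set numbers in which many genes were low on replicate 2. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.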

Results

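The series followed yeast cells whose only remaining source of histone H3 carried arginine in place of the lysines at positions 4, 36 and 79, the residues that are methylated by Set1, Set2 and Dot1. Cells had been grown in galactose, in which wild-type H3 was also made, and were then moved to glucose, which repressed the wild-type gene. The study asked which genes the mutant histone regulates. The arrays described here are the 2 replicate cultures of the mutant at 18 hours after the shift. Each array held 9335 probe sets, with a median signal of 25.5 on replicate 1 and 25.7 on replicate 2. Without wild-type or earlier samples, the values below give transcript levels in the mutant at this time and the spread between its 2 arrays, not changes caused by the mutation. Each culture had 1 array, so that spread mixes differences of culture, labelling and array. All values are deposited MAS5 signals in arbitrary units, as mean ± SD over the replicate cultures (n = 2), and signals of different genes are not on a common scale.

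Histone transcripts were detected on both arrays. The probe set that the annotation assigns to both histone H3 genes, HHT1 and HHT2, gave 1311 ± 70.2 (SD, n = 2). It cannot tell the genes apart, and the annotation does not say whether it detects the mutant copy. The other H3 probe sets, also shared by both genes, gave 113.2 ± 4.18 and 1.33 ± 0.117, the last of these at or under background on both arrays. The shared histone H4 probe set (HHF1 and HHF2) gave 309.1 ± 7.85, and the shared H2A probe sets (HTA1 and HTA2) gave 630.4 ± 5.23 and 399.6 ± 9.43. The H2B genes have probe sets of their own, with 332.0 ± 12.0 for HTB1 and 149.9 ± 15.6 for HTB2. HTZ1, which encodes the H2A.Z variant, gave 54.4 ± 2.98, the linker histone gene HHO1 gave 43.8 ± 2.48, and CSE4, for the centromeric H3 variant, gave 28.4 ± 0.121. Between the arrays, the 5 genes of the histone list with their own probe sets differed by a median log2 of -0.01, at the 33.8th percentile of random lists.

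The methyltransferases that act on the mutated lysines were SET1 (lysine 4), with 50.9 ± 5.29, SET2 (lysine 36), with 5.80 ± 0.641, and DOT1 (lysine 79), with 11.5 ± 1.76. Of the 18 genes for H3 methylation and the linked H2B ubiquitination, 18 were above the foreign-probe background on both arrays. That background was exceeded by 96.3% of the 6504 probe sets with a single gene, so passing it says little about expression. Members of this list named by the rule on signal were RAD6, the ubiquitin-conjugating enzyme that acts on H2B, with 56.8 ± 4.49, SET1, and SWD2, a subunit of the Set1 complex, with 40.0 ± 1.38. Of the 17 silencing factors, 17 were above background. HST1, a homologue of SIR2, gave 151.4 ± 17.1, SAS4 gave 75.6 ± 3.72 and ESC1 gave 59.7 ± 1.41. SIR2, the silencing deacetylase, gave 49.2 ± 1.61, SIR3 gave 38.7 ± 1.65 and SIR4 gave 23.8 ± 1.89. The 13 silencing genes bright enough to compare had a median log2 difference of -0.07 between the arrays, at percentile 3.41, and those for H3 methylation had 0.10, at the 87.9th percentile. Neither list stood apart. The silencing median turned to 0.05 (50.2nd percentile) over the 9 genes outside 2 ranges of probe set numbers, chosen after the data were seen, where many genes were lower on replicate 2 and which hold SIR1, SIR2, SIR3 and RIF1. The silencing median was 0.00 (24.4th percentile) over all 17 genes with no filter on dim signals. Without that filter the 18 H3 methylation genes moved outward, to 0.14 (96.4th percentile), and still did not stand apart.

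All 9 measured genes of galactose use were above the foreign-probe background after 18 hours in glucose. So were 96.3% of the 6504 probe sets with a single gene, and the count does not show that these genes were expressed. GAL1, the galactokinase, gave 6.95 ± 0.399, GAL7 gave 17.4 ± 2.29, GAL2, the galactose permease, gave 12.8 ± 1.02, and GAL10 gave 32.7 ± 8.53. The regulators gave 12.8 ± 1.42 for GAL3, 13.0 ± 0.351 for GAL4 and 63.8 ± 7.51 for GAL80. GCY1 and PGM2 of the same list gave 237.2 ± 26.8 and 160.2 ± 2.31. GAL10 was 1.45-fold lower on replicate 2, and its probe set, like those of GAL1, GAL2, GAL3 and GAL7, lies in 1 of these ranges of probe set numbers. The hexose transporters HXT1 and HXT3 gave 98.5 ± 13.3 and 784.5 ± 40.5, and HXT6 and HXT7, near-identical genes whose probes can share transcripts, gave 689.7 ± 29.5 and 547.3 ± 5.55. The 10 transporters compared had a median log2 difference of 0.07 (92.3rd percentile). Among the 16 measured genes of glycolysis and fermentation, ADH1, the main alcohol dehydrogenase of fermentation, gave 1347 ± 20.0, TPI1 gave 1209 ± 19.7 and FBA1 gave 1157 ± 39.2. The list's median log2 difference was -0.01 between the arrays (82.8th percentile). Among the 23 measured genes repressed by glucose, HXK1 gave 425.3 ± 6.20, GLK1 gave 316.3 ± 2.76 and ADH2 gave 190.3 ± 4.76. The 16 of them bright enough to compare had a median log2 difference of -0.02 (15.2nd percentile).

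All 7 a-specific and all 4 alpha-specific mating genes were above the foreign-probe background on both arrays. So were 96.3% of the 6504 probe sets with a single gene, and the counts do not show that either set was expressed. The a-specific genes included the pheromone genes MFA1, with 366.5 ± 59.6, and MFA2, with 320.5 ± 13.9, and STE2, the receptor for alpha factor, with 72.5 ± 2.35. BAR1, the protease that degrades alpha factor, gave 107.6 ± 0.938, AGA2 gave 105.1 ± 1.92, STE6 gave 63.3 ± 8.56 and ASG7 gave 9.96 ± 1.56. The 6 a-specific genes bright enough to compare had a median log2 difference of -0.03 (30.4th percentile). SAG1, the alpha-agglutinin, gave 93.7 ± 2.43. MF(ALPHA)1 gave 21.1 ± 2.31, MF(ALPHA)2 gave 10.7 ± 1.62 and STE3, the receptor for a-factor, gave 7.58 ± 0.559. Of 44 genes of meiosis and sporulation, markers of another cell state, 40 exceeded the foreign-probe background and their median signal was 8.32, with SPR6 at 61.4 ± 4.58, DIT1 at 27.5 ± 2.30 and SPS100 at 24.7 ± 1.30. Of 8 genes often used as selectable markers, TRP1 was the gene not above background, with 1.62 ± 0.155. URA3 gave 88.8 ± 1.95, LEU2 gave 189.5 ± 4.74 and HIS3 gave 176.9 ± 1.17. The 7 marker genes compared had a median log2 difference of 0.01 (54.2nd percentile), and 8 haploid-specific mating genes had 0.01 (36.8th percentile), with STE4, the beta subunit of the pheromone-response G protein, at 91.6 ± 4.90.

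**Figure D1:**
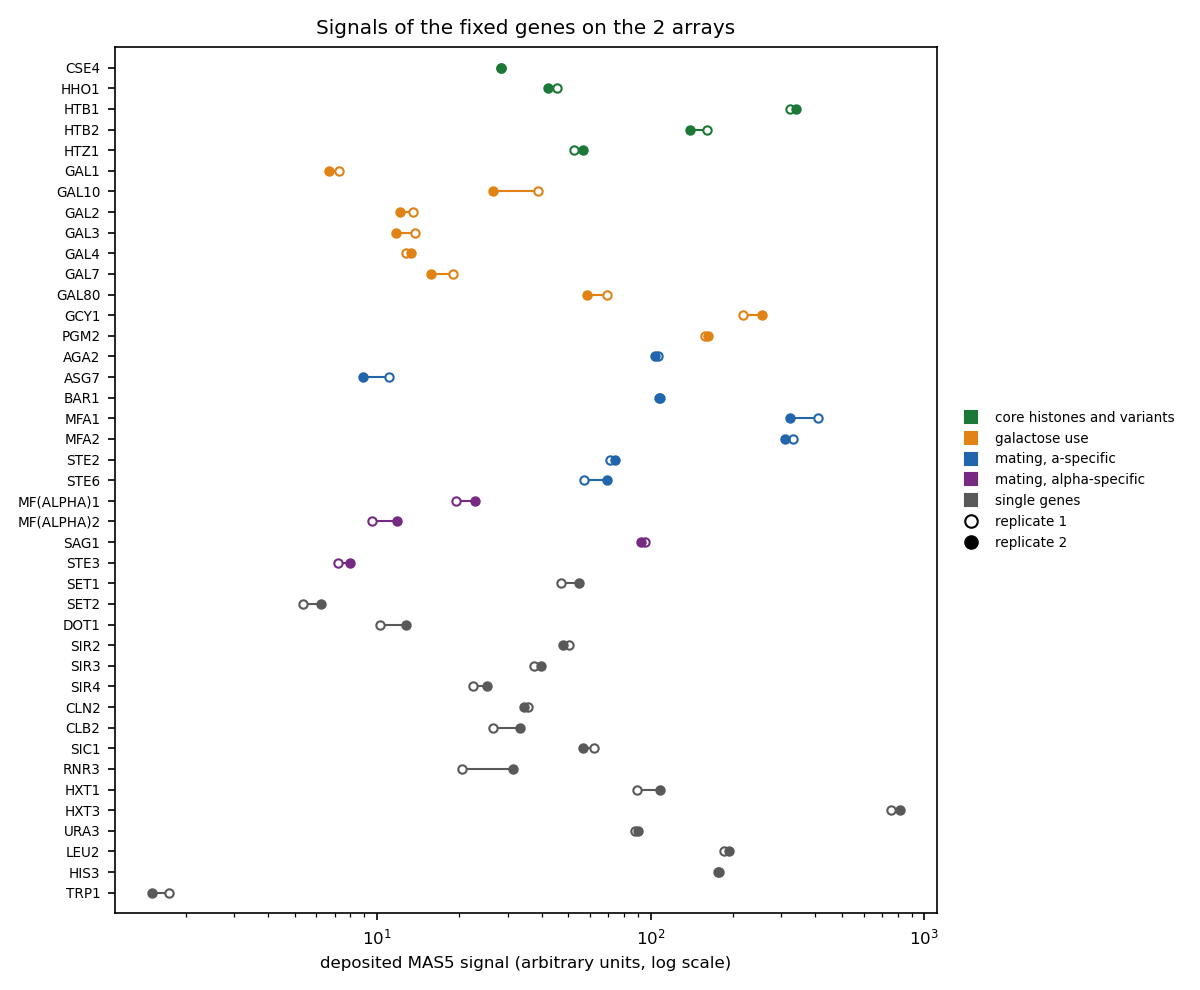
Deposited MAS5 signals (horizontal axis, arbitrary units, log scale) of the genes fixed before the data were examined, 1 row per gene, with open points for replicate 1, filled points for replicate 2 and colours for the gene list. Most pairs of points lie close together, GAL10 and RNR3 lie farther apart, and both TRP1 points lie under 2; rows are not comparable with each other because probe sets differ in affinity.

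CLN2, a G1 cyclin, gave 35.0 ± 0.740, CLB2, a mitotic cyclin, gave 29.9 ± 4.75, and SIC1, the inhibitor of B-type cyclin kinase, gave 59.3 ± 3.73. The median log2 difference between the arrays was 0.02 for 23 G1/S genes (39.3rd percentile), 0.08 for 19 G2/M genes (91.7th percentile) and -0.03 for 21 M/G1 genes (8.93rd percentile). The 12 DNA damage genes compared had 0.05 (71.4th percentile). In that list, RNR4 and RNR2, subunits of ribonucleotide reductase, gave 439.7 ± 11.1 and 367.3 ± 40.0, and HUG1 gave 146.6 ± 4.91. RNR3, the damage-inducible large subunit of that enzyme, gave 26.0 ± 7.84 and was 1.54-fold higher on replicate 2, the largest increase among the 4092 genes compared. Its probe set is of a kind that can match more than one transcript, as are those marked for families in HXT6, HXT7, MFA1 and RPS29B.

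The 80 measured cytosolic ribosomal protein genes had a median signal of 638.3, with RPS22A at 1264 ± 106.7, and 60 of them were lower on replicate 2, with a median log2 difference of -0.06. Random lists of equally bright genes centred on -0.04, and the list lay at the 8.09th percentile. The count depended on the scaling: after quantile normalization 44 genes were lower and 35 higher (median -0.01), and after loess 45 were lower and 35 higher (median -0.02). Against equally bright genes the list did not move toward the middle, at percentile 6.17 after quantile normalization and 4.20 after loess. Neither stood apart. The 47 ribosome biogenesis genes had a median difference of 0.04 (73.3rd percentile), with NOP58, a core protein of box C/D snoRNPs, at 532.6 ± 3.07. The 32 general stress genes had 0.03 (81.1st percentile), with HSP12 at 983.3 ± 31.4 and HOR7 at 1190 ± 68.6. The 35 nuclear genes of the respiratory chain and ATP synthase had 0.05 and lay at the 97.3rd percentile, with 24 of them higher on replicate 2. QCR7, a subunit of the cytochrome bc1 complex, gave 502.1 ± 29.3, COX12 gave 495.4 ± 10.1 and CYC1, cytochrome c, gave 479.1 ± 31.2. Of the 26 lists compared, 0 stood apart, where chance alone would give 1.3. Among the others, ergosterol synthesis had -0.01 (49.7th percentile, ERG25 829.2 ± 56.6), amino acid synthesis 0.03 (83.8th, LYS20 691.9 ± 40.8), methionine and sulfate use -0.04 (10.02nd, MET17 833.8 ± 48.8) and the TCA cycle -0.01 (38.2nd, MDH1 550.6 ± 35.5). The proteasome had 0.04 (89.1st, PUP3 463.8 ± 24.2), cell wall integrity -0.06 (7.09th, SED1 1208 ± 107.9), the phosphate regulon -0.02 (19.8th, PHO5 179.2 ± 6.86) and the iron regulon 0.04 (67.4th, FIT3 275.1 ± 7.27). Medians close to 0 have no settled direction: those of the G1/S, TCA cycle, ergosterol, glycolysis and haploid-specific mating lists changed sign after loess, and that of the marker genes was smaller than the constant that median centring takes from every gene. Taking the mean of a gene's probe sets in place of the brightest one put 2 lists outside the range, the cytosolic ribosomal proteins (-0.07, 0.555th percentile) and the respiratory chain (0.05, 97.8th percentile).

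**Figure D2:**
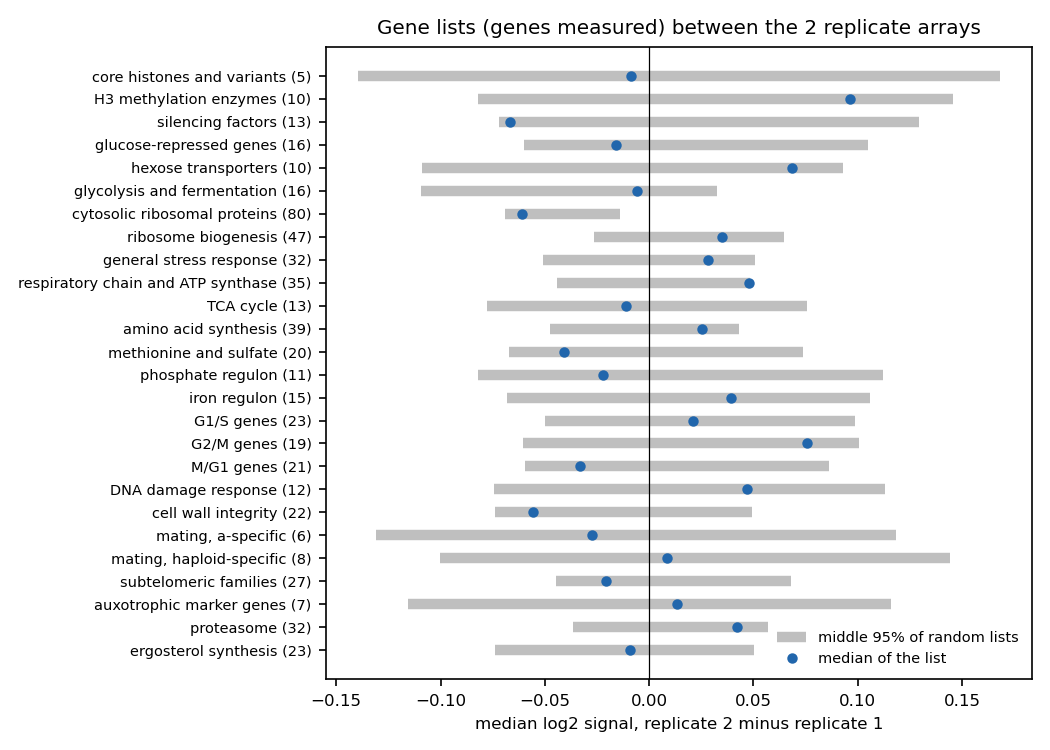
Median log2 difference in signal, replicate 2 minus replicate 1 (horizontal axis), of each gene list with its number of genes; points are list medians and grey bars the middle 95% of 10000 random lists matched on signal. All 26 points lie on their bars, with the respiratory chain (97.3rd percentile) and the silencing factors (percentile 3.41) closest to an end.

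Of the 4092 brighter genes, 99.4% lay within 1.5-fold between the arrays, and of the 25 outside it 22 were lower on replicate 2. Pearson's r of log2 signal was 0.983 and Spearman's rho 0.994 across the 9290 probe sets above 0 on both arrays. These are correlations across genes, which are not independent replicates. The SD of the log2 difference was 0.69 for probe sets with signals from 1 to 4 and 0.12 for those from 256 to 2048. Of the 9290, 338 differed by more than 2-fold, 163 higher and 175 lower on replicate 2, but 5 of the 5090 with a mean signal of at least 21.6. Among the 4092 genes 3 did. SAP190, which encodes a partner of the Sit4 phosphatase, was 2.45-fold lower on replicate 2, TAF2, a TFIID subunit, was 2.34-fold lower and YDL124W was 2.12-fold lower. The next lowest were RVS161, YCR043C, RSM10, CHA4, CLB3, PAT1 and RPS29B, with log2 differences from -0.93 to -0.76. In the other direction RNR3, PHD1, YOR072W-B, PYC1, GPG1, DPB4, ELC1, MOT2, BOI2 and LTV1 had log2 differences from 0.62 to 0.51. PYC1, a pyruvate carboxylase, gave 157.6 on replicate 1 and 234.5 on replicate 2. With 1 array on each side, none of these gene differences has a test. The lowest genes had neighbouring probe set numbers: of 63 genes with a log2 difference below -0.4, 48 lay in 2 ranges of numbers that hold 24.6% of the genes compared. The ranges were drawn from these same genes, so the count describes them and is no test. As signs of RNA quality, the ratio of the 3′ to the 5′ control probe set was 1.61 on replicate 1 and 1.57 on replicate 2 for ACT1 (actin), and 2.85 and 3.25 for SPT15, the TATA-binding protein gene.

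**Figure D3:**
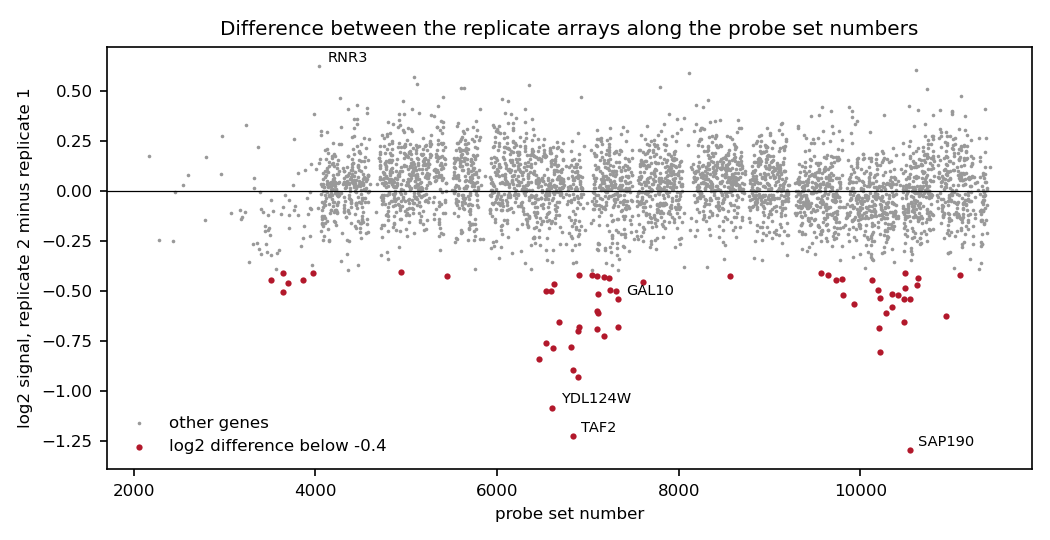
Log2 difference in signal, replicate 2 minus replicate 1 (vertical axis), of the brighter genes against the number of their probe set (horizontal axis, no unit); red points are the 63 genes below -0.4. The red points crowd into 2 ranges of numbers chosen after the data were seen, with SAP190 the lowest at -1.30, and of the 35 genes above 0.4, 6 lie in those ranges.

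Chromosome ends are where silent chromatin forms in yeast. Of 201 measured genes among the 10 outermost of each chromosome arm, 190 were above the foreign-probe background on both arrays, 94.5% (95% Wilson interval 90.5 to 96.9%), against 5214 of 5266 elsewhere, 99.01% (98.7 to 99.2%). That background, a signal of 1.86 on replicate 1 and 1.69 on replicate 2, was exceeded by 96.3% of the 6504 probe sets with a single gene and so sorts few genes. The shares were not tested against each other, and they count different probe sets, which differ in affinity. The 201 genes are the measured ones among 320 annotated there, so the share covers only part of the end genes. Among the 33 measured members of subtelomeric families, of 72 listed, 27 were compared, with a median log2 difference of -0.02 (11.5th percentile). Near-identical copies in these families can share probes. Not all members are among the outermost genes: leaving the families out took the genes elsewhere from 5266 to 5255. Family members were named by their signal and not by their position: PAU23 gave 317.7 ± 31.2, TIR1 gave 296.7 ± 6.43 and IMD2 gave 289.9 ± 16.6. Their signals are therefore not examples of expression at chromosome ends. No wild-type array was compared, so these shares do not measure an effect of the mutant on silencing.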

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

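The threshold from sporulation genes, the 5 and 15 outermost genes, and the removal of 2 ranges of probe set numbers were tests chosen after the data were seen. The count of probe sets over 2-fold apart between the arrays, 338 with no filter, was 5 with a signal of at least 21.6, 3 with at least 35.2 and 0 with an offset of 50, and between 288 and 340 with the other scalings and removals. The median signal over all list genes, 106.9, was 107.9 to 108.3 with either array alone and 101.9 with the mean of a gene's probe sets. The number of lists standing apart, 0, became 1 with no filter on dim probe sets and 2 with the mean of a gene's probe sets, and was 0 in the others. Median centring, 1 of these, shifts a list and its random lists alike and could not change it. The 1 list was galactose use, median log2 difference -0.16 over 9 genes, 0.560th percentile, and 5 of its genes (GAL1, GAL2, GAL3, GAL7 and GAL10) lie in those ranges of numbers. Galactose use was not among the 26 lists compared with the filter, which left 4 of its genes, under the minimum of 5. Those 26 lists kept their calls with no filter. The cause of the change to 2 with the mean of a gene's probe sets was not tested. The share of genes near chromosome ends above background was 94.5% for the 10 outermost genes. It was 89.6% for the 5 outermost genes (98.96% elsewhere) and 96.2% for the 15 outermost (99.02% elsewhere). With the sporulation threshold it was 57.7% (74.2% elsewhere), and with that threshold and without the subtelomeric families 53.9% (74.2% elsewhere). The sporulation threshold lowers both shares and sets levels of different probe sets against each other, so its shares say nothing about chromosome ends. Distances of 10 and 30 kb were not run, because the deposited data name no genome build. The count of probe sets above background ran from 6232 to 6330 with foreign probe sets, and was 4324 of 6504 (66.5%) with the sporulation threshold. No paired analysis was possible because there is 1 group. Signals under about 16 limit what can be read: their log2 differences had an SD of 0.32 or more.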

Other observations

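The tests of the tRNA pattern, of the regional effect and of a local defect were chosen after the results were seen. The copy-number prediction was written before its own result was seen, though for a pattern found in these data. Among classes outside the fixed lists, taken from the RefSeq table after the data were seen, tRNA and small nucleolar RNA genes stood apart from random lists between the arrays. Of the 27 tRNA genes among the brighter genes, 24 were lower on replicate 2, with a median log2 difference of -0.26, below all 10000 random lists. Of the 26 small nucleolar RNA genes, 18 were lower, with a median of -0.06 at the 0.700th percentile, among them SNR67 with 322.6 ± 66.7 (SD, n = 2). Of the 19 mitochondrially encoded genes, taken without the filter on dim signals, 14 were lower, with a median of -0.21 at percentile 0.1. That median rests on dim signals, since 4 of the genes were bright enough to compare, and of these OLI1 and ATP6 were lower (log2 -0.41 and -0.37) and COX1 and COX3 higher (0.11 and 0.39). OLI1, subunit 9 of the ATP synthase, gave 585.8 ± 117.2, and COX1 gave 680.3 ± 36.2. These genes were named after their values were seen.

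The tRNA pattern has technical explanations that the data bear on in part. A trend with signal level is argued against, since after loess the tRNA median was -0.295 against -0.07 to 0.08 for the middle 95% of random lists. The probe sets of these 27 tRNA genes have numbers from 3358 to 3905, and 253 other probe sets in that range also had a low median, -0.09, so the position may account for part of it. The tRNA median was lower than theirs by a log2 difference of -0.1655 (95% bootstrap interval -0.21 to -0.03), which leaves open how much. Less small structured RNA in the second sample or its labelling is a candidate explanation. The snoRNA percentile of 0.7 goes with it but comes from these same data, so it is no independent support. The snoRNA median, -0.06, was also far smaller in size than the -0.26 of the tRNA genes. Near-identical tRNA copies share sequence between their probe sets, and no biological explanation was tested because both samples belong to 1 group.

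Genes with neighbouring probe set numbers were low together on replicate 2. Of the 63 genes below -0.4, 27 had another such gene within 3 numbers, against a median of 4 in random draws, whose middle 95% reached up to 9, while of the 35 genes above 0.4 the count was 0. A change in copy number of the whole of chromosome III is argued against, since the median over its 95 genes was -0.0163 (95% bootstrap interval -0.05 to 0.02). That chromosome held 7 of the 63 low genes, against 14 on chromosome II and 11 on chromosome XII. Its median does not bear on the low genes elsewhere, or on a change in part of a chromosome. An effect on neighbouring genes of a chromosome is argued against by the spacing: the low genes formed 15 pairs at a distance of 68 to 69 numbers and 14 pairs at 12 to 13, but 0 at 28 to 51, while the highest count at any distance from 5 to 100 had a median of 4 in random draws, whose middle 95% reached up to 6. A local defect on 1 of the arrays may explain the pattern but stays open. It predicts that second probe sets of the low genes, far away by number, are less low. Only 1 gene (KIN2) had a bright one, with a log2 difference of 0.20 against -0.54 for its low probe set. That goes with the prediction, but 1 gene is too few to decide. Probe positions were not used here.

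The threshold set by foreign probe sets passed 40 of 44 sporulation genes, so "above background" here says little about expression. The median log2 difference of a chromosome's genes ran from -0.05 on chromosome XII to 0.10 on chromosome VI, leaving out the mitochondrial genome. The 15 polyadenylated bacterial control probe sets had a median log2 difference of -0.03 (SD 0.10).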
